A study of Mus musculus with 10 samples.

How the data were processed

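Single-cell RNA sequencing was carried out on colonic epithelial cells of 10 male mice, 5 wild-type (WT) and 5 in which the aryl hydrocarbon receptor gene Ahr was targeted (KO). Per the labels' protocols, both genotypes carried a tamoxifen-inducible Cre recombinase and EGFP at the Lgr5 locus and a Cre-activated Tomato reporter, and the KO mice also carried floxed Ahr alleles. The mice were 8 to 10 weeks old and received 2.5 mg of tamoxifen on 4 days, and their colons were taken 2 weeks after it. Crypts were released with 15 mM EDTA for 35 min, filtered through a 40 µm mesh and sorted for Tomato, with or without GFP, on either of 2 instruments. The gate therefore held stem cells that had recombined and the cells descended from them. KO mice were cohoused with littermate controls. Each library came from 1 mouse, and libraries are named here by genotype and by the number or letter in their titles (2, 3, 4, 5 and g).

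The authors deposited, per the file headers, 1 matrix of whole-number UMI counts per library, with a gene list and a barcode list, made from the 10x 3′ v3 kit. The submitters' processing notes name Cell Ranger 2.1.0 and the mouse build mm10, whereas the file headers name software version 3.0.2; the settings used to call cells are not given in the sources used here. The deposited gene lists were of 2 kinds. A shorter list of 31056 features, with TdTomato, GFP and EGFP among them, was used for WT replicates 2, 3 and 4 and KO replicates 2, 3 and 5. A longer list of 54624 features was used for WT replicates 5 and g and KO replicates 4 and g. The 31035 genes in both were analysed, matched by identifier; 264 of them had another symbol in the other list and 69 symbols occurred more than once. At least 95.7% of the UMIs of each library lay in these genes.

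Of 62741 deposited barcodes, 49358 were kept, each with at least 1000 UMIs, at least 500 genes and at most 25% mitochondrial UMIs. Doublets were scored with Scrublet as built into scanpy 1.11.5. Its automatic thresholds marked from 0% of cells in some libraries up to 6.60%, so the highest-scoring cells were removed instead at a rate of 0.8% per 1000 cells of the library, 2854 cells in all. Also removed were 2 clusters in which over 50% of cells were predicted doublets, which took out a further 268 cells. Counts were normalised per cell, log-transformed and centred per gene within each library, and 40 principal components of 2000 variable genes were clustered with the Leiden algorithm (leidenalg 0.10.2, 20 neighbours, resolution 1), which gave 39 clusters. A cluster took the name of the class whose markers, fixed before the data were examined, had the highest mean score, provided that the score reached 0.25. A cluster with more markers of another class among its 10 leading genes also stayed unnamed. So would a cluster that held none of its class there and whose median depth was below 0.333 of that of its libraries, which was the case for none. The floor of 0.25 was set after the scores were seen. A T cell-like cluster was removed, which took out 75 cells (44 of them in WT replicate g and 14 in KO replicate g), and 46161 epithelial cells were left. Free RNA in the droplets was not estimated, so markers of another class at a low level are not shown to be expressed by the cells of a class. Cell names therefore come from rebuilt clusters, not from an annotation by the authors.

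Counts were summed per library over all epithelial cells and over each class, since the mouse and not the cell is the replicate, and a library entered where it had at least 20 cells of the class. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the edgeR filter on low counts and a model of feature list plus genotype over all 10 libraries. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p below 0.05 was called. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Positive log2 values are higher in KO throughout. The difference of the KO effect between stem-like and colonocyte-like cells was tested as an interaction in edgeR with the library as a block. Gene lists fixed before the data were examined, 28 with at least 5 tested genes, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with the correlation estimated, and with fry. Class shares are percentages of a library's epithelial cells, and genes per cell were counted after each cell had been thinned to 3000 UMIs; both were compared with two-sided exact permutation tests over the 252 splits of the libraries, in scipy 1.17.1. Chromosome positions were taken from GENCODE vM21 on GRCm38, the assembly behind mm10, by gene identifier; 30934 of the genes had one.

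The samples, groups, tests, covariates, cell type markers, gene lists, rule for named genes and most alternatives were fixed before the data were examined. By that rule, Ahr, Lgr5 and the AhR targets were always named. In each comparison the genes with the highest and lowest log2 fold changes were named among called genes with at least 20 CPM in the higher genotype, with unnamed gene models left out, along with up to 4 members of each list with the smallest p, and where fewer than 10 genes were called also the next genes by p. Called genes outside this rule are named as well, and they were chosen after their values were seen. The edgeR tests were checked on simulated data in which 200 genes of each comparison, and 182 for the interaction, were changed. In all epithelial cells, 78% of genes changed by 1 log2 unit and 95% of those changed by 2 were called, and 5.98% of calls were false. In stem-like cells these shares were 90%, 100% and 5.94%. For the interaction test 43.0% and 94.4% were recovered, with 0.8% of calls false. Camera at the preset correlation and the permutation test were checked on simulated data as well, and fry and camera with an estimated correlation were not. The simulated counts were drawn gene by gene, so genes did not vary together and only feature list and genotype set the libraries apart. These checks therefore cannot show whether the tests, camera among them, keep to their error rates where genes vary together or libraries differ otherwise.

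Alternatives covered DESeq2 1.42.0 in place of edgeR, other normalisation factors, no filter on low counts, no feature list term, a replicate block, either feature list alone, doublets kept, stricter limits on mitochondrial UMIs and on depth, another clustering resolution, naming cell by cell, other thinning depths, and leaving out each library in turn. The other 3 were chosen after seeing the data: without both libraries named g, a mitochondrial limit set by feature list, and a naming floor of 0. Results that rest on certain genes are not reported here. Total depth ranged from 50309513 to 93920873 UMIs per library. Intervals and floors based on UMIs cover counting error only. The labels give the mice as separate animals but no litter, sequencing date or instrument for any of them.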

Results

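The study asked whether loss of the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor, changes the differentiation or the gene expression of Tomato-positive cells sorted from the colon, which are stem cells and the cells derived from them. Single-cell RNA-seq libraries from 5 WT and 5 KO mice held between 50309513 UMIs (WT replicate g) and 93920873 UMIs (WT replicate 4), with a median of 6834 UMIs per barcode in WT replicate 5 and up to 17079 in KO replicate g. After filtering, 25322 WT and 20839 KO epithelial cells were compared, carrying 329249200 and 328450272 UMIs. They fell into stem-like (4001 WT and 3019 KO cells), transit-amplifying-like (5844 and 5028), colonocyte-like (3125 and 3680), goblet-like (5138 and 3955), enteroendocrine-like (699 and 584) and tuft-like cells (393 and 340), and 6122 WT and 4233 KO cells stayed unnamed. In both libraries named g, most cells lay in 4 clusters of their own (66.1% of cells in WT replicate g and 61.4% in KO replicate g, against at most 0.0505% in any other library). Median mitochondrial content of epithelial cells was 14.1% in WT replicate 2, which has the shorter feature list, and 4.31% in WT replicate g, which has the longer one.

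Ahr itself was read in every library. In all epithelial cells its level was 11.0, 10.6, 10.2, 10.6 and 12.8 CPM in WT replicates 2, 3, 4, 5 and g, and 16.4, 16.1, 15.2, 17.1 and 20.8 CPM in KO replicates 2, 3, 4, 5 and g. Every KO library thus lay above every WT library (11.1 ± 1.03 against 17.1 ± 2.16 CPM, mean ± SD, n = 5 each), and the log2 fold change was 0.63 (SE 0.09, edgeR adjusted p = 0.0294). The UMIs come from the 3′ end of transcripts, and the labels do not state which part of Ahr is floxed. A tag outside the deleted part checks nothing, so these levels are no check of the knockout. The log2 fold change was 0.64 within the shorter and 0.61 within the longer feature list, and the call was lost when WT replicate 2, 3, 4 or 5 or KO replicate 2, 3 or 5 was left out.

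No target of the receptor was called. Cyp1a1, Cyp1a2 and Aldh3a1, which encode classical AhR-induced enzymes, had 0 UMIs in both genotypes, which allows up to 0.00911 CPM in WT and 0.00913 CPM in KO. Cyp1b1 had 2 UMIs in WT and 0 in KO, and Ahrr, the AhR repressor, had 6 and 2. All 8 targets with enough counts lay higher in KO, among them Tiparp (13.0 ± 1.90 against 15.5 ± 1.39 CPM, log2 0.26, SE 0.10), Gsta1 (log2 0.31, SE 0.34), Nfe2l2 (log2 0.17, SE 0.12), Nqo1 (log2 0.12, SE 0.27), Cyp2s1 (log2 0.06, SE 0.10) and Ugt1a6a (log2 0.05, SE 0.26), with n = 5 each. Their edgeR adjusted p-values ran from 0.402 for Tiparp to 0.970 for Ugt1a6a, and 0 of the 8 passed when adjusted over the list alone. The camera test of the list gave an adjusted p of 0.131, and 0.96 with an estimated correlation. With 1 library left out, Gsta1 ran from 0.09 (without KO replicate 4) to 0.69 (without WT replicate 5), Nfe2l2 from 0.10 (KO replicate 2) to 0.27 (KO replicate g) and Cyp2s1 from 0.01 (WT replicate g) to 0.14 (WT replicate 2), as log2 fold changes. Nqo1 ran from −0.02 (KO replicate 4) to 0.36 (WT replicate 5) and Ugt1a6a from −0.12 (KO replicate 2) to 0.35 (WT replicate 5). The direction of Nqo1, Nfe2l2, Tiparp, Cyp2s1 and Ugt1a6a turned under at least 1 alternative.

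Over all epithelial cells 11 of 14322 genes were called by edgeR, 4 higher and 7 lower in KO. The strongest was Amn, which encodes amnionless, a subunit of the receptor for vitamin B12 bound to intrinsic factor. Amn fell from 53.5 ± 2.86 CPM in WT to 14.7 ± 3.18 CPM in KO (n = 5 each; log2 −1.88, SE 0.11, edgeR adjusted p = 7.8e-05). Its level was lower in 5 of 5 KO libraries than in any WT library. Acp1, a low molecular weight phosphatase, fell from 138 ± 15.0 to 87.5 ± 4.69 CPM (log2 −0.66, SE 0.07, adjusted p = 0.0108). Mrps12, a protein of the mitochondrial ribosome, fell from 102 ± 7.14 to 68.5 ± 4.86 CPM (log2 −0.58, SE 0.07, adjusted p = 0.0126). Adi1, an enzyme of the methionine salvage pathway, rose by log2 0.68 (SE 0.09, adjusted p = 0.0219). Its mean of 13.2 ± 10.3 CPM in WT and 22.3 ± 18.2 CPM in KO spread widely, since it read higher in libraries with the shorter list than in those with the longer one.

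The remaining called genes lay below the 20 CPM of the naming rule or were unnamed gene models, and were chosen after their values were seen. Slc25a29 fell from 9.49 ± 1.27 to 5.76 ± 0.320 CPM (log2 −0.71), Srp54a from 8.66 ± 1.27 to 6.40 ± 1.08 CPM (log2 −0.44) and Hdac9 from 0.283 ± 0.0568 to 0.0611 ± 0.0108 CPM (log2 −2.16). Prkd1 had 116 UMIs in WT and 0 in KO, at least 38.6-fold lower in KO with a floor of 3 counts over the group. Sntg2 rose from 0.0337 ± 0.0320 to 0.529 ± 0.161 CPM (log2 3.98), and 5033406O09Rik rose from 11.4 ± 1.89 to 18.1 ± 2.67 CPM (log2 0.67). Among genes that did not pass, Lgr5, the stem cell marker, was at 23.6 ± 8.53 CPM in WT and 24.2 ± 6.32 CPM in KO (log2 0.05, SE 0.19, edgeR adjusted p = 0.947). It was lower in KO when WT replicate 4 or 5 or KO replicate 5 or g was left out. Itln1, intelectin-1, was at 19.6 ± 8.63 and 5.06 ± 1.42 CPM (log2 −1.96, adjusted p = 0.0820). An unadjusted p below 0.05 was given by 1522 genes against 716 expected, and 176 genes (1.23%) had every KO library above or below every WT library, against 0.794% by chance.

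Within the shorter feature list edgeR called 175 genes, 10 of the 11 among them, and within the longer list 0 (2 mice against 2). The log2 fold change of Amn in all epithelial cells was −1.68 in the former and −2.20 in the latter, and its call held with any 1 library left out. With 1 library left out in turn the calls of Acp1, Hdac9, Slc25a29 and Sntg2 were kept in 9 of 10 fits, Mrps12 in 8, Prkd1 in 6, Adi1 in 5, Ahr and 5033406O09Rik in 3 and Srp54a in 1. Without both g libraries 47 genes were called, including all 11, and DESeq2 called 126. Leaving out WT replicate 3 left 1 call, leaving out WT replicate 2 left 6 and leaving out KO replicate g gave 21.

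**Figure D1:**
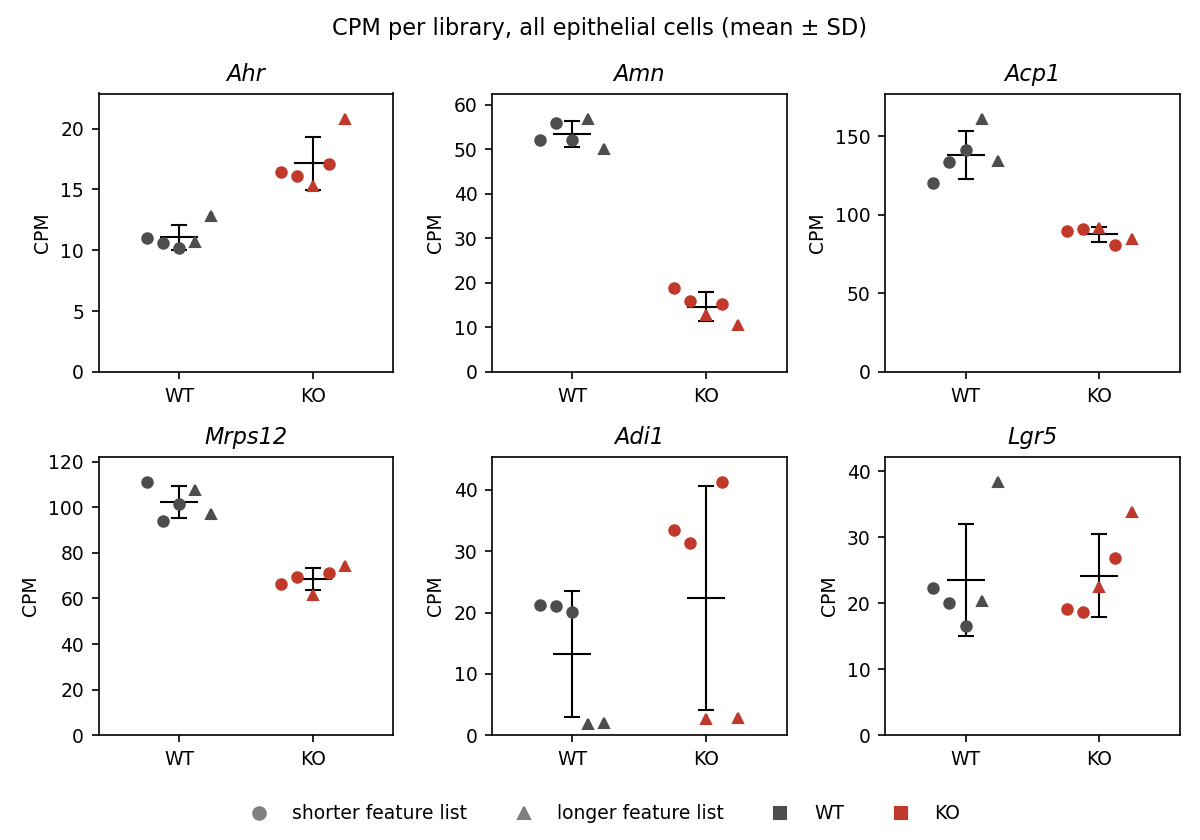
CPM of Ahr, Amn, Acp1, Mrps12, Adi1 and Lgr5 in all epithelial cells of each library (points), with the mean and SD of each genotype (n = 5 each). Ahr lies at 15.2 CPM or more in every KO library and at 12.8 or less in every WT library, and Amn lies lower in every KO library than in any WT library.

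The genes called over all epithelial cells were gathered on the chromosome of Ahr, an examination chosen after they were seen. Of the 11, 10 lay on chromosome 12, where 502 of the 14311 tested genes with a position (3.51%) lie and 0.386 of 11 would be expected (Fisher's exact p = 2.75e-14). Ahr, the targeted gene, is counted in this test, although its place was set in advance. Ahr (ENSMUSG00000019256) spans positions 35497974 to 35535038 of chromosome 12 in GRCm38, on the minus strand, and the called genes span 28675231 to 111944484. They form groups on either side of a stretch from 60 to 90 Mb, in which 0 of 184 tested genes had an unadjusted edgeR p below 0.001. Adi1, Sntg2, Acp1, Hdac9 and Ahr lie between 28675231 and 35535038, Prkd1 and Srp54a between 50341231 and 55115367, and Slc25a29, Amn (ENSMUSG00000021278, 111271095 to 111276426) and 5033406O09Rik between 108825873 and 111944484. The exception was Mrps12 (ENSMUSG00000045948), on chromosome 7 from 28739641 to 28741820. Among genes that were not called, 16.7% of those on chromosome 12 had an unadjusted p below 0.05, against 10.3% elsewhere (Fisher's exact p = 2.58e-05). Acp1 was lower and Ahr higher in KO in 6 of 6 classes, and Amn was lower in 5 of 5 classes in which it was tested. Adi1 and 5033406O09Rik were higher in 5 of 5 classes and Srp54a lower in 4 of 4, while Slc25a29 was lower in 4 of 5 (log2 −1.05 to 0.03). Of the genes called in transit-amplifying-like cells 2 of 3 lay on chromosome 12 (Fisher's exact p = 0.00353), and in colonocyte-like cells 1 of 1 (Fisher's exact p = 0.0342). It was 1 of 3 in enteroendocrine-like (Fisher's exact p = 0.0991) and 1 of 4 in tuft-like cells (Fisher's exact p = 0.125). No gathering was shown in those 2 classes.

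**Figure D2:**
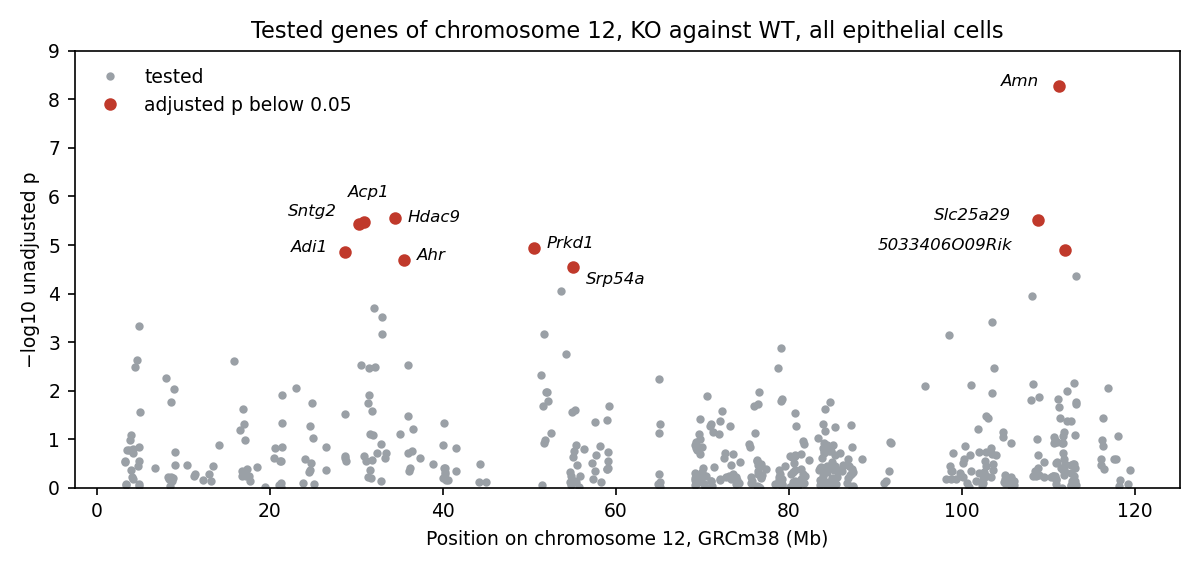
Unadjusted edgeR p, as −log10, of each tested gene on chromosome 12 (KO against WT, all epithelial cells) by its position in Mb on GRCm38, with called genes named in red. The called genes lie between 28.7 and 112 Mb, with Ahr at 35.5 Mb, and none lies between 60 and 90 Mb.

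Of the 28 fixed lists tested over all epithelial cells, 6 passed the camera test. Of 100 splits of the 10 libraries into 5 and 5, with the real one among them, 99 gave at least 6. Chance is therefore not argued against for this count. Lists within classes other than stem-like cells were not set against such splits. Colonocyte markers rose together, with 15 of 17 higher in KO (adjusted p = 0.000666; adjusted p = 0.809 with an estimated correlation), among them the chloride-bicarbonate exchanger Slc26a3 (50.7 ± 11.8 against 75.3 ± 17.3 CPM) and Slc37a2 (9.67 ± 3.11 against 16.4 ± 4.41 CPM). Within colonocyte-like cells 14 of 17 of these markers were lower in KO (camera adjusted p = 0.162; adjusted p = 0.819 with an estimated correlation), while the share of these cells was 11.9% in WT and 17.1% in KO. Genes of fatty acid oxidation rose, 18 of 18 higher (adjusted p = 0.000666; 0.96 with an estimated correlation, as an adjusted p), with Cpt1a, which carries fatty acids into mitochondria, at 59.6 ± 7.40 and 74.8 ± 12.7 CPM. Within colonocyte-like cells 8 of 17 of these genes were higher (camera adjusted p = 0.643) and within stem-like cells 9 of 15 (camera adjusted p = 0.432), so no rise of the list was called within either class. Glycolysis and hypoxia genes (17 of 18 higher, adjusted p = 0.0103; adjusted p = 0.809 with an estimated correlation), with Hk2 and Egln3 among them, and heat shock genes (12 of 12, adjusted p = 0.0283; adjusted p = 0.96 with an estimated correlation), such as Hsp90aa1 and Hsph1, rose. MHC class II genes fell (7 of 7 lower, adjusted p = 0.0283; adjusted p = 0.96 with an estimated correlation), with Cd74, the invariant chain, at 79.0 ± 105 CPM in WT and 30.6 ± 26.3 in KO (log2 −0.93, and −0.26 without WT replicate g). Enteroendocrine markers fell as well (13 of 14 lower, adjusted p = 0.0337; adjusted p = 0.96 with an estimated correlation), with the hormone gene Insl5 at 144 ± 73.5 and 49.1 ± 34.1 CPM and Pyy at 522 ± 412 and 231 ± 129 CPM (log2 −1.21, and −0.75 without WT replicate g).

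No single member of these lists was called over all genes in edgeR; adjusted over the list alone, 1 glycolysis and hypoxia gene and 1 enteroendocrine marker passed. Neither camera with an estimated correlation nor fry called any list, and among the lists that did not pass the camera adjusted p ran from 0.0647 for ribosomal protein genes to 0.938 for tuft markers. Leaving out KO replicate 2 gave 10 lists, and leaving out both g libraries gave 11. Of the list members named, Slc26a3, Egln3 and Hsp90aa1 lie on chromosome 12, where the called genes were gathered. They start at positions 31390871, 54178981 and 110690605, and the other members named lie on other chromosomes. The share of enteroendocrine-like cells was 11.0% in WT replicate g and 8.08% in KO replicate g, and at most 2.49% in the other WT and 2.95% in the other KO libraries. The log2 fold change of Insl5 was −1.80, and −2.12 to −1.54 with any 1 library left out.

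Markers of other cell types, summed over each of 7 fixed lists, were low in the epithelial sums. B or plasma cell markers read 0.403 ± 0.175 CPM in WT and 1.16 ± 0.335 CPM in KO (n = 5 each, exact permutation p = 0.0159, adjusted over the 7 lists 0.111), led by the immunoglobulin gene Igkc at 0.0803 and 0.622 CPM. Myeloid markers read 4.42 ± 2.27 and 9.30 ± 4.36 CPM (exact permutation p = 0.0794, adjusted 0.278), led by the complement gene C1qa at 2.29 and 6.89 CPM, which is also the leading gene of a goblet-like cluster. They ran from 2.73 to 4.66 CPM in the WT libraries and from 8.90 to 13.0 CPM in the KO libraries other than g, and were at 8.26 CPM in WT replicate g and 2.16 CPM in KO replicate g. T cell markers read 2.49 and 2.095 CPM, endothelial markers 2.84 and 2.84, smooth muscle or glial markers 2.60 and 2.42, fibroblast markers 0.0601 and 0.102 and erythroid markers 0.0413 and 0.0745 CPM. None of the 7 passed after adjustment.

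In stem-like cells, the class that the labels name, 4 genes were called among 11483. Amn fell from 70.1 ± 3.39 to 18.9 ± 1.39 CPM (n = 5 each; log2 −1.88, SE 0.07, edgeR adjusted p = 9.36e-08) and Acp1 fell from 150 ± 17.0 to 98.2 ± 7.34 CPM (log2 −0.61, SE 0.07, adjusted p = 0.0120). Ahr rose from 14.2 ± 1.14 to 23.1 ± 1.55 CPM (log2 0.71, SE 0.08, adjusted p = 0.0120) and Agr3, a protein disulfide isomerase family member, from 17.5 ± 3.53 to 32.6 ± 2.47 CPM (log2 0.91, SE 0.12, adjusted p = 0.0321). All 4, with Ahr as the targeted gene among them, lie on chromosome 12 (Fisher's exact p = 1.43e-06). The next genes by p did not pass: Adi1 (log2 0.83), Tmem18 (log2 0.74), Josd2 (log2 −0.40), Prkar2b (log2 1.63), Pik3cg (log2 1.41) and Clu (log2 −0.80), with edgeR adjusted p from 0.0808 to 0.297. Of these, Adi1, Tmem18, Prkar2b and Pik3cg also lie on chromosome 12, and Josd2 and Clu lie on chromosomes 7 and 14. Lgr5 was at 95.7 ± 20.1 CPM in WT and 100.3 ± 13.0 in KO (log2 0.07, SE 0.14, adjusted p = 0.999). An unadjusted p below 0.05 was given by 553 genes, against 574 expected.

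Of the calls in stem-like cells that of Agr3 was kept in 1 of the 10 fits with 1 library left out (adjusted p up to 0.155), Acp1 in 5 and Ahr in 6. The Amn call in stem-like cells held with any 1 library left out, at a log2 fold change of −1.83 within the shorter and −1.98 within the longer list. The count fell to 1 without WT replicate 3, WT replicate g, KO replicate 3 or KO replicate 5, and was 8 without both g libraries, 16 and 0 within the shorter and longer lists and 15 by DESeq2.

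More fixed lists passed in stem-like cells than genes. They were 13, and 21 of the 100 splits gave at least as many, so chance is not argued against for this count. The stem markers among them are also those from which the class was named. Markers of stem cells (10 of 12 higher in KO, camera adjusted p = 0.00669; adjusted p = 0.409 with an estimated correlation) and Wnt targets (15 of 15, adjusted p = 1.29e-05; adjusted p = 0.252 with an estimated correlation) rose. Among them were Ascl2 (82.3 ± 12.2 against 107 ± 24.3 CPM), Axin2 (80.5 ± 11.6 against 93.5 ± 8.46 CPM) and Ccnd1 (236 ± 38.1 against 273 ± 23.1 CPM). Notch genes (6 of 9, adjusted p = 0.0432; adjusted p = 0.435 with an estimated correlation), S phase genes (24 of 27, adjusted p = 0.0466; adjusted p = 0.926 with an estimated correlation) and heat shock genes (12 of 12, adjusted p = 0.0312; adjusted p = 0.629 with an estimated correlation) rose too. Goblet markers fell (12 of 13 lower, adjusted p = 1.4e-08; adjusted p = 0.112 with an estimated correlation). Among them Clca1 was at 6.99 ± 3.42 and 2.37 ± 0.666 CPM, Fcgbp at 13.0 ± 2.27 and 8.85 ± 1.13 CPM, and Spink4 at 76.8 ± 21.2 and 56.7 ± 8.17 CPM, and 5 of the list passed in edgeR when adjusted over the list alone. These levels are low, free RNA in the droplets was not estimated, and the counts do not show that stem-like cells themselves express goblet genes. In goblet-like cells 8 of the markers were higher and 7 lower (camera adjusted p = 0.808). The log2 fold change of Spink4 in stem-like cells turned to 0.0615 at resolution 0.5 and to 0.0592 with cells named by highest score.

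Also lower in these cells were enteroendocrine markers (6 of 8, camera adjusted p = 0.0218; adjusted p = 0.372 with an estimated correlation) and cholesterol synthesis genes (21 of 21, adjusted p = 0.000236; adjusted p = 0.629 with an estimated correlation). So were nuclear genes of oxidative phosphorylation (70 of 77, adjusted p = 0.00598; adjusted p = 0.926 with an estimated correlation) and Nrf2 targets (11 of 14, adjusted p = 0.00499; adjusted p = 0.189 with an estimated correlation). MHC class II genes (5 of 5, adjusted p = 0.00669; adjusted p = 0.439 with an estimated correlation), fetal or YAP genes (7 of 10, adjusted p = 0.0166; adjusted p = 0.252 with an estimated correlation) and antimicrobial genes (5 of 9, adjusted p = 0.0432; adjusted p = 0.252 with an estimated correlation) fell as well. Of the MHC class II genes, Cd74 was at a log2 fold change of −0.81, and −0.03 without WT replicate g. The antimicrobial list was led by Ang4 (4.56 ± 3.25 against 1.01 ± 0.713 CPM), which was also lower over all epithelial cells (log2 −1.59, SE 0.41, edgeR adjusted p = 0.313), and 1 member of it and 1 of the fetal or YAP list passed when adjusted over the list alone. Without KO replicate 5, 7 lists passed, and 8 without WT replicate 2.

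In transit-amplifying-like cells, 3 of 12408 genes were called, all lower in KO. Mrps12 fell from 122 ± 7.25 to 83.4 ± 3.50 CPM (n = 5 each; log2 −0.54, SE 0.06, edgeR adjusted p = 0.0160). Acp1 fell from 183 ± 19.5 to 117 ± 6.70 CPM (log2 −0.64, SE 0.08, adjusted p = 0.0172) and Amn from 62.2 ± 9.79 to 17.2 ± 6.73 CPM (log2 −1.84, SE 0.21, adjusted p = 0.0160). Wnt targets (14 of 15 higher) and heat shock genes (12 of 12) rose, and MHC class II (7 of 7 lower), cholesterol synthesis (17 of 21) and fetal or YAP genes (6 of 9) fell, at camera adjusted p of 0.00209 to 0.0191, and 0.807 for each of the 5 with an estimated correlation, as an adjusted p. Gja1, which encodes connexin 43, and Anxa1 passed when adjusted over the fetal or YAP list alone (log2 −1.37 and −0.45). A cluster led by MHC class II genes, among them H2-Eb1 and Cd74, held 349 WT and 149 KO cells of this class before doublets were taken out, so changes within the class are not separated from its mix of clusters. Other clusters of the class are not given here, and this cluster alone does not show which way the mix shifted. The count was 0 without WT replicate 3 or 4 or KO replicate 3, 4 or 5, 6 without WT replicate g or KO replicate 2, and 32 without KO replicate g. Within the shorter list it was 231, within the longer 0, without both g libraries 102 and by DESeq2 50.

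In colonocyte-like cells, Amn was the 1 gene called of 10986, and fell from 74.4 ± 13.2 to 20.1 ± 3.26 CPM (n = 5 each; log2 −1.86, SE 0.15, edgeR adjusted p = 0.00151). Slc25a29 (log2 −1.05) and the depalmitoylase gene Abhd17a (log2 −0.65) came next and did not pass. Heat shock genes (10 of 11), G2/M phase genes (19 of 25) and transit-amplifying markers (12 of 16) were higher by camera, at adjusted p of 0.00198, 0.0107 and 0.0401, and 0.438, 0.768 and 0.819 with an estimated correlation, as adjusted p. MHC class II genes (6 of 6) and enteroendocrine markers (8 of 8) fell, at adjusted p of 0.00023 and 1.05e-05, and 0.768 and 0.411 with an estimated correlation. In them the log2 fold change of Cd74 was −1.79, and −0.65 without WT replicate g, and that of Pyy was −1.44, and −0.80 without WT replicate 5. The clusters of this class also differed in their balance of WT and KO cells, and the tests do not separate that from a change within cells. Free RNA was not estimated, and the counts do not show that colonocyte-like cells themselves express enteroendocrine genes. The count was 2 without KO replicate 2 and 10 without KO replicate g, and 203 within the shorter list, 0 within the longer, 63 without both g libraries and 14 by DESeq2. Whether the KO effect differed between stem-like and colonocyte-like cells was tested directly. The interaction test in edgeR called 0 of 12032 genes, with 221 at an unadjusted p below 0.05 against 602 expected. It called 83 without both g libraries and 1 without KO replicate g. Differences of effect between other classes were not tested.

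In goblet-like cells 14 of 11500 genes were called. Cma1, which encodes mast cell chymase and is among the leading genes of 2 goblet-like clusters, rose from 28.8 ± 1.72 to 56.3 ± 12.9 CPM (n = 5 each; log2 0.96, SE 0.11, edgeR adjusted p = 0.00201). Itln1, a lectin that binds microbial sugars and is also among the leading genes of 2 goblet-like clusters, fell from 107 ± 60.6 to 27.2 ± 5.91 CPM (log2 −1.98, SE 0.32, adjusted p = 0.0245). Clps, which encodes colipase, fell from 340 ± 19.1 to 219 ± 27.2 CPM (log2 −0.63, SE 0.09, adjusted p = 0.00636), and Mrps12 (log2 −0.68), Acp1 (log2 −0.59) and the mitochondrial ADP/ATP carrier Slc25a4 (log2 −0.34) fell too, while Adi1 rose (log2 0.75). The others were chosen after their values were seen. Agr3 (log2 1.503) and 5033406O09Rik (log2 0.80) rose, and Aspg (log2 −1.59), 4933406C10Rik (log2 −1.08), Slc25a29 (log2 −0.79) and Amn (log2 −2.40) fell. Coch had 0 UMIs in WT and 127 in KO, at least 47.7-fold higher in KO with a floor of 3 counts over the group. Of the 14, 9 lie on chromosome 12 (Fisher's exact p = 1.29e-10). The mix of goblet-like cells differed as well, with 1 cluster of 627 WT and 225 KO cells before doublets were taken out, and the test of the class does not separate a change in this mix from a change within cells. Other goblet-like clusters are not counted here, so that cluster alone does not show which way the mix shifted.

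Cholesterol synthesis genes (21 of 21), MHC class II genes (5 of 5) and nuclear genes of oxidative phosphorylation (70 of 78) fell in goblet-like cells, at camera adjusted p of 2.89e-07, 0.00355 and 0.00271, and heat shock genes rose (12 of 12, 0.0264). With an estimated correlation the adjusted p was 0.613, 0.613, 0.915 and 0.826. Insig1 was at 80.6 ± 10.7 CPM in WT and 59.6 ± 22.5 in KO, and Msmo1 at 154 ± 27.5 and 115 ± 36.5. H2-Ab1, an MHC class II gene, had a log2 fold change of −1.14, and −0.69 without WT replicate g. The Cma1 call held with any 1 library left out, with log2 fold changes of 0.85 and 1.12 within the shorter and longer lists, whereas that of Itln1 was lost without WT replicate 2 or 5 or KO replicate 2, 3, 4 or 5. With 1 library left out the calls of Slc25a29 and Slc25a4 were kept in 3 of 10 fits, Amn in 4 and Adi1 in 9. The count was 8 without KO replicate 5, 72 within the shorter list, 0 within the longer, 37 without both g libraries and 42 by DESeq2.

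In enteroendocrine-like cells, 3 of 8633 genes were called. Uchl1, a neuronal and neuroendocrine ubiquitin hydrolase, fell from 101 ± 41.9 to 24.9 ± 10.4 CPM (n = 5 each; log2 −1.96, SE 0.28, edgeR adjusted p = 0.0159). Fabp5, a fatty acid binding protein, fell from 377 ± 105 to 158 ± 44.0 CPM (log2 −1.22, SE 0.20, adjusted p = 0.0352) and Adi1 rose (log2 1.07, SE 0.18, adjusted p = 0.0356). Goblet markers were higher (9 of 11, camera adjusted p = 0.00015; adjusted p = 0.53 with an estimated correlation). Free RNA was not estimated, and the counts do not show that enteroendocrine-like cells themselves express goblet genes. Of the list, 5 passed when adjusted over the list alone, among them Spink4 (138 ± 96.2 against 561 ± 739 CPM) and Retnlb (11.5 ± 8.16 against 103 ± 206 CPM). Without KO replicate 3 the log2 fold change of Retnlb went from 2.95 to 0.38 and that of Spink4 from 1.92 to 0.79. With 1 library left out the calls of Uchl1, Fabp5 and Adi1 were kept in 5, 3 and 2 of 10 fits. The gene count was 0 without WT replicate 3 or KO replicate 2, 3 or 5, 1 without WT replicate 2, 5 or g, 8 without KO replicate 4, 12 within the shorter list, 0 within the longer and 5 by DESeq2.

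In tuft-like cells, 4 of 5728 genes were called, each at an edgeR adjusted p of 0.0485. Car8 (65.5 ± 16.5 against 21.5 ± 9.09 CPM, log2 −1.57, SE 0.27), Acp1 (123 ± 12.1 against 68.8 ± 15.1 CPM, log2 −0.87, SE 0.16) and Gsta4 (124 ± 26.6 against 61.2 ± 25.2 CPM, log2 −1.05, SE 0.19) fell. Agap1 rose (92.0 ± 19.4 against 157 ± 31.1 CPM, log2 0.80, SE 0.14; n = 5 each). Tuft markers rose (11 of 11 higher, camera adjusted p = 4.11e-08; adjusted p = 0.257 with an estimated correlation), with Dclk1 at 1305 ± 543 and 1924 ± 706 CPM and Trpm5, a taste transduction channel, at 488 ± 155 and 734 ± 345 CPM. Of the list, 8 passed when adjusted over the list alone. The class was named from these same markers and free RNA was not estimated. A change in the purity of the class is therefore not separated from a change within its cells. Wnt targets rose (8 of 10, adjusted p = 0.00795; adjusted p = 0.257 with an estimated correlation). Ribosomal protein genes (74 of 77 lower), G2/M phase genes (9 of 10), nuclear genes of oxidative phosphorylation (62 of 75), Nrf2 targets (6 of 6), transit-amplifying markers (7 of 8), cholesterol synthesis genes (16 of 18) and goblet markers (8 of 8) fell at camera adjusted p of 4.11e-08 to 0.00153, and 0.239 to 0.757 with an estimated correlation. With 1 library left out the call of Car8 was kept in 2 of 10 fits, and those of Acp1, Agap1 and Gsta4 in 1. These libraries held as few as 34 tuft-like cells. No call was left without WT replicate 2, 4 or g or KO replicate 5, 12 were made without KO replicate 3, and 28 by DESeq2. Within the shorter list 4 genes were called and without both g libraries 4, with 0 of the 4 above among them in either case.

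The make-up of the sorted cells was then compared. Colonocyte-like cells were 11.9 ± 2.13% of epithelial cells in WT and 17.1 ± 4.73% in KO (n = 5 each), a difference of 5.21 percentage points (exact permutation p = 0.0556, adjusted over 6 classes 0.333). Stem-like cells were 19.0 ± 10.3% and 15.9 ± 7.73% (exact p = 0.484), transit-amplifying-like cells 19.9 ± 9.70% and 22.5 ± 9.25% (exact p = 0.571) and goblet-like cells 20.1 ± 1.99% and 19.3 ± 1.73% (exact p = 0.508). Enteroendocrine-like cells were 3.90 ± 3.96% and 3.35 ± 2.69% (exact p = 0.738), and tuft-like cells 1.97 ± 1.61% and 2.11 ± 2.28% (exact p = 0.825). None passed, and the adjusted p of these 5 was 0.825. Without WT replicate g the KO minus WT difference turned from −3.10 to 1.46 percentage points for stem-like, from 2.55 to −1.46 for transit-amplifying-like and from −0.550 to 1.22 for enteroendocrine-like cells. That of tuft-like cells turned from 0.147 to −0.834 without KO replicate g, and also turned without WT replicate 3 or 4. Cells left unnamed, by the floor on marker scores or by leading genes of another class, were 23.3 ± 5.41% and 19.9 ± 2.73% (exact permutation p = 0.230). Several unnamed clusters scored highest for colonocyte markers but below the floor, so the colonocyte-like share depends on where that floor was set.

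Within the shorter list (3 mice against 3, where no p below 0.10 is possible) KO minus WT was 7.12 percentage points for colonocyte-like, −2.31 for stem-like, 3.54 for transit-amplifying-like, −2.02 for goblet-like, −0.286 for enteroendocrine-like and −0.405 for tuft-like cells. Within the longer list (2 against 2) it was 2.36, −4.29, 1.08, 0.960, −0.946 and 0.975. The sort on Tomato and the release of crypts set which cells were captured. Shares in both g libraries stood far from the rest. Stem-like cells were 37.2% in WT replicate g and 29.5% in KO replicate g, and at most 16.004% in the other WT and 14.6% in the other KO libraries. The stem-like cells of WT and KO replicate g nearly all came from cluster 12 (743 and 689 cells before doublets were taken out). That cluster scored 0.522 for stem and 0.447 for transit-amplifying markers, so the shares of these 2 classes in the g libraries rest largely on its name.

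**Figure D3:**
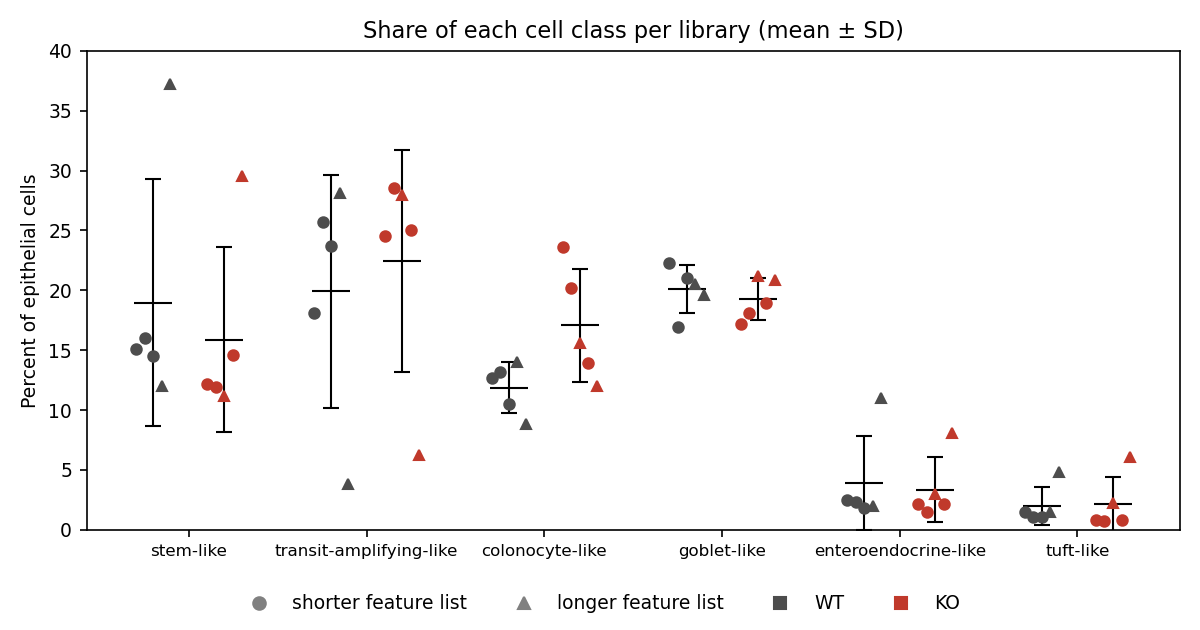
Percentage of epithelial cells in each class for each library (points), with the mean and SD of each genotype (n = 5 each). Colonocyte-like cells average 11.9% in WT and 17.1% in KO, and the g libraries have the highest stem-like shares, 37.2% and 29.5%.

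The number of genes detected per cell, a measure of how broad expression is, was counted after each cell had been thinned to 3000 UMIs. In all epithelial cells the median was 1379 ± 42.2 genes in WT and 1385 ± 57.5 in KO (n = 5 each, exact permutation p = 0.889), and in stem-like cells 1381 ± 42.2 and 1382 ± 60.2 (exact permutation p = 0.992). Cells with fewer UMIs were left out, 1611 WT and 832 KO cells overall and 128 and 51 among stem-like cells. Before thinning the medians were 3674 ± 868 and 3845 ± 324 genes in all epithelial cells (exact permutation p = 0.690) and 3491 ± 1058 and 3623 ± 572 in stem-like cells (exact permutation p = 0.770). Within the shorter list KO minus WT was 3.33 genes over all epithelial cells and −5.67 in stem-like cells, and within the longer list it was 9.25 in both.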

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

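The tests of explanations below were chosen after the results were seen. In groups of 5 libraries, a library was taken out for a closer look where its gap to the nearest other library exceeded 0.71 of the range of its genotype. Of 74 such groups, chance alone would pick out about 1 in 20. Both libraries named g were picked out for stem-like cells (37.2% in WT replicate g, with the other WT libraries at 12.0% to 16.004%, and 29.5% in KO replicate g, with the other KO libraries at 11.2% to 14.6%). They were picked out again for enteroendocrine-like cells (11.0% in WT replicate g and 8.08% in KO replicate g, against at most 2.49% and 2.95% in the others) and for tuft-like cells (4.81% and 6.04%, against at most 1.49% and 2.21%). KO replicate g also had a low share of transit-amplifying-like cells, 6.21%, with the other KO libraries at 24.6% to 28.6%. WT replicate g, which the rule did not pick out for this class, had the lowest share of the WT libraries, 3.86%. The stem-like and transit-amplifying-like shares of both g libraries rest largely on the name of 1 cluster, as given above. Lgr5 in all epithelial cells was 38.4 CPM in WT replicate g, above 16.6 to 22.3 CPM in the other WT libraries, and Amn in colonocyte-like cells was 96.9 CPM there, above 63.0 to 72.8.

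The g libraries also held 4 clusters nearly to themselves. At most 0.0505% of the cells of the other libraries with the longer list lay in those clusters. WT replicate 2, whose median of 17843 UMIs per cell is nearest to the 19615.5 of KO replicate g, had 0% of its cells there. The clusters were picked because nearly all their cells came from the g libraries. These low shares were therefore largely set by that choice, and they do not decide on feature list or depth as a cause. A difference in preparation or sequencing stays open: 61.4% of the cells of KO replicate g and 66.1% of those of WT replicate g lay in those clusters, but the labels give no batch for any library, so it cannot be told apart from a difference between the mice. Both genotypes have 1 such library, so genotype does not separate them, and no biological explanation was tested.

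Acp1 in transit-amplifying-like cells was 106 CPM in KO replicate 5, below 118 to 122 CPM in the other KO libraries. The shorter feature list has reporter genes that enter no comparison. TdTomato had 4820, 6423 and 2010 UMIs in WT replicates 2, 3 and 4, and 3002, 2838 and 2329 in KO replicates 2, 3 and 5. GFP had 8, 12 and 11 UMIs in those WT libraries, and 10, 16 and 18 in those KO libraries. They were taken out for a closer look as a signal in features that no comparison uses, above what a true count of 0 would allow, and there was no library without the reporter to compare with.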

How the results depend on the processing

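Results for both g libraries left out, the mitochondrial limit by feature list and the naming floor of 0 come from alternatives chosen after seeing the data; the others were fixed before. Over the alternatives fixed before, each library left out in turn included, the results that answer a comparison kept their direction and side of the threshold, or a count within 1.5 times, in 263 cases; 66 lost the call or fell in count, 37 gained it or rose in count and 18 turned direction. For single genes named, the same numbers are 2349, 262, 87 and 21. For the alternatives added later they are 44, 2, 7 and 3, and for single genes 351, 11, 8 and 0. The longer feature list leaves 2 mice against 2, and the limit of 10% mitochondrial UMIs removes most cells of the libraries with the shorter list; for the other changes the cause was not tested. Depth limits what can be tested, with 14322 genes tested over all epithelial cells, 8633 in enteroendocrine-like and 5728 in tuft-like cells.

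In all epithelial cells the 11 called genes became 25 with no filter on low counts, 4 with no feature list term, 175 with the shorter and 0 with the longer feature list only, 17 with doublets kept, 0 with at most 10% mitochondrial UMIs, 47 without the g libraries and 126 by DESeq2. In stem-like cells the 4 became 28 with no filter, 2 with no feature list term, 16 and 0 with the shorter and longer list, 2 with at most 10% mitochondrial UMIs, 9 with cells named by highest score, 8 without the g libraries and 15 by DESeq2. In transit-amplifying-like cells the 3 became 28 with no filter, 231 and 0 with either list, 102 without the g libraries and 50 by DESeq2. In colonocyte-like cells the 1 became 203 and 0 with either list, 0 with at most 10% mitochondrial UMIs, 63 without the g libraries, 0 with a naming floor of 0 and 14 by DESeq2. In goblet-like cells the 14 became 137 with no filter, 7 with no feature list term, 72 and 0 with either list, 37 without the g libraries and 42 by DESeq2. In enteroendocrine-like cells the 3 became 96 with no filter, 0 with no feature list term, 12 and 0 with either list, 1 by highest score and 5 by DESeq2. In tuft-like cells the 4 became 164 with no filter, 0 with no feature list term, 0 with the longer list, 4 with the shorter list and 4 without the g libraries (0 of them shared with the 4 in either, whose adjusted p within the shorter list was 0.278), 11 with doublets kept, 0 with at most 10% mitochondrial UMIs, 9 with at least 3000 UMIs per cell, 1 at resolution 0.5, 2 by highest score, 0 with the mitochondrial limit by feature list and 28 by DESeq2.

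The 6 lists of all epithelial cells became 0 with an estimated correlation, 0 by fry, 12 with the longer list, 13 with at most 10% mitochondrial UMIs and 11 without the g libraries; the 13 of stem-like cells became 0, 0 and 8 with an estimated correlation, fry and the longer list. The interaction count of 0 became 83 without the g libraries. The Ahr change of 0.63 lost its call with no feature list term (0.63), the longer list only (0.61) and at most 10% mitochondrial UMIs (0.55).

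The correlations below do not settle whether the replicate numbers pair the mice. Numbers 4 and 5 differ in feature list between the genotypes, whereas 2, 3 and g do not. Deviations from the genotype means correlated at 0.63, 0.79, −0.64, −0.71 and 0.83 for numbers 2, 3, 4, 5 and g, values that carry the feature list. With the feature list also taken out they were −0.165, −0.0211, 0.302, −0.124 and 0.295, and in neither case did every library correlate best with its own number. Before it was taken out, WT replicates 2, 3 and g each correlated best with the KO library of their own name. Afterwards WT replicates 4 and g did. With the replicate block the count was 6 in all epithelial cells, 18 in stem-like, 5 in transit-amplifying-like and 1 in tuft-like cells, and within 1.5 times the main count in the other classes.

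Shares turned direction for enteroendocrine-like cells without the g libraries (0.0358) and for tuft-like cells with at least 3000 UMIs per cell (−0.0969), by highest score (−0.0213), with the mitochondrial limit by feature list (−0.0578), on the logit scale (−0.117) and without the g libraries (−0.123). Single genes turned with the longer list only: Cd44 in transit-amplifying-like cells (−0.11), Lgr5 (−0.0616), Nfe2l2 (−0.0207), Nqo1 (−0.36), Tiparp (−0.0289) and Ugt1a6a (−0.44) in all epithelial cells, and Nrarp (−0.0212) and Tac1 (0.10) in stem-like cells. Cyp2s1 turned with the shorter list (−0.0926) and Spink4 in stem-like cells at resolution 0.5 (0.0615) and by highest score (0.0592).

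Leaving out each library in turn gave 1 (WT replicate 3) to 21 (KO replicate g) calls in all epithelial cells, with 6 without WT replicate 2, and 1 (WT replicate 3 or g, KO replicate 3 or 5) to 6 (KO replicate g) in stem-like cells. It gave 0 (WT replicate 3 or 4, KO replicate 3, 4 or 5) to 32 (KO replicate g) in transit-amplifying-like cells, with 6 without WT replicate g or KO replicate 2. It gave 1 to 10 (KO replicate g) in colonocyte-like cells, with 2 without KO replicate 2, and 8 (KO replicate 5) to 19 (KO replicate g) in goblet-like cells. In enteroendocrine-like cells it gave 0 (WT replicate 3, KO replicate 2, 3 or 5) to 8 (KO replicate 4), with 1 without WT replicate 2, 5 or g. In tuft-like cells it gave 0 (WT replicate 2, 4 or g, KO replicate 5) to 12 (KO replicate 3), with 1 without WT replicate 3 or KO replicate 2, 4 or g and 2 without WT replicate 5. It gave 4 (KO replicate 5) to 10 (KO replicate 2) lists in all epithelial and 7 (KO replicate 5) to 13 in stem-like cells, with 8 without WT replicate 2, and 0 to 1 (KO replicate g) genes in the interaction. Ahr ranged from 0.56 to 0.70, with the call lost without WT replicate 2, 3, 4 or 5 or KO replicate 2, 3 or 5. Shares ranged from −6.51 to 1.46 for stem-like (1.46 without WT replicate g), −1.46 to 6.62 for transit-amplifying-like, −1.73 to 1.22 for enteroendocrine-like and −0.834 to 0.858 for tuft-like cells, 3.58 to 6.47 for colonocyte-like and −1.61 to −0.282 for goblet-like cells. Genes per cell ranged from −17.2 to 18.5 in all epithelial and −22.3 to 14.2 in stem-like cells. Lgr5 ranged from −0.0601 to 0.23 in all epithelial and −0.0242 to 0.18 in stem-like cells, Nqo1 from −0.0181 to 0.36 and Ugt1a6a from −0.12 to 0.35.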

Other observations

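The tests of explanations and what the other splits of the libraries should show were chosen after the results were seen. Of the 2 patterns weighed, one is the g libraries, described above, and the other is the gathering of called genes on chromosome 12, where 10 of the 11 of all epithelial cells lie. Ahr, the targeted gene, is among them, so its place was set in advance. The positions of the larger sets called under other settings were not tested. For the 11, an effect of AhR loss on genes across the genome is argued against as the whole cause, since it would put 0.386 of them on chromosome 12. A candidate explanation is DNA of another mouse strain carried along with the floxed Ahr allele, which also predicts, beyond the called genes that prompted it, an excess there of genes that were not called but had an unadjusted p below 0.05 (16.7% against 10.3%, Fisher's exact p = 2.58e-05). By parts whose bounds were set from the positions seen, and which therefore test nothing on their own, that share was 23.8% below 60 Mb, 9.78% from 60 to 90 Mb and 17.1% above 90 Mb (Fisher's exact p = 0.0169 for the last against other chromosomes), where 3 of 143 genes were called. For the genes above 90 Mb, Amn at 75.8 Mb from Ahr among them, linked DNA and other causes cannot be told apart, since the stretch between showed no such excess and its bounds were chosen from the data. It stays a hypothesis, since the labels give no strain for the allele and an effect of AhR loss on any single gene there was not separated from linked DNA.

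Each count of calls was set against 100 splits of the 10 libraries into 5 and 5, drawn from 126 with the real one among them. At least as many genes were called in 3 splits for all epithelial cells (11 genes, highest other 757), 4 for stem-like cells (4 genes, highest other 280) and 2 for transit-amplifying-like cells (3 genes, highest other 637). They were called in 2 for colonocyte-like cells (1 gene, highest other 491) and 2 for goblet-like cells (14 genes, highest other 14), so that chance is argued against at 0.05 for these 5 counts, each taken alone. The shares of splits were not adjusted over the counts. The 5 counts come from the same mice and share genes, Amn in each, so they are not separate evidence. Chance is not argued against for enteroendocrine-like cells (8 splits, 3 genes, highest other 16) or tuft-like cells (6 splits, 4 genes, highest other 16). Nor is it for the lists of all epithelial cells (99 splits, 6 lists, highest other 19) or the lists of stem-like cells (21 splits, 13 lists, highest other 16). The real count of the interaction was 0, which every split reaches, so its 100 splits (highest other 1) test nothing. Lists of the other classes were not set against splits. The splits with 757, 637 and 491 genes set WT replicates 2, 3, 4 and g with KO replicate g against WT replicate 5 with KO replicates 2, 3, 4 and 5. The split with 280 genes in stem-like cells set WT replicates 2, 3 and 5 with KO replicates 2 and 4 against the rest. They call many times the real count. Among the shorter-list libraries the first of these splits is the genotype split itself, WT replicates 2, 3 and 4 against KO replicates 2, 3 and 5. Among the longer-list libraries both splits set the g libraries against WT replicate 5 and KO replicate 4. The high counts therefore do not show a structure apart from genotype and the g libraries. A later test took all 40 splits with 1 g library and 2 longer-list libraries on each side. The real split alone reached its count for the 5 counts above (highest other 4, 0, 2, 0 and 8 genes), at a share of 0.025 of the splits. For enteroendocrine-like cells, tuft-like cells and the lists of stem-like cells 3 of the 40 did, and for the lists of all epithelial cells all 40. All 40 also did for the interaction, as they must at a count of 0.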
